A study of Arabidopsis thaliana with 30 samples.

How the data were processed

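RNA was sequenced from shoots of Arabidopsis thaliana in 30 libraries, 3 in each of 10 groups. Per the labels, the plants carry the genotype EAR, VP16 or Col-0, the tissue was kept in RNA Later, total RNA was extracted and libraries followed a standard Illumina protocol. The series concerns plant growth and genome interrogation, in which artificial zinc-finger transcription factors with an activating or a repressing domain are expressed in plants. EAR is the usual name of a plant transcriptional repression motif, VP16 that of a transcriptional activation domain from herpes simplex virus, and Col-0 is the common laboratory accession. The target sequences of the factors were not given in the sources used here. In the labels 5 groups are named lines, 4 are pool backgrounds and 1 is Col-0. The pool of a line was read from the number in its name, so that EAR-13-068 was set against the EAR pool 13 background and VP16-02-003 against the VP16 pool 2 background.

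The deposited values are whole-number counts of reads per gene, 1 table per library, with no normalisation visible in them. Per the submitters' processing notes, TopHat2 2.0.5, HTSeq and the TAIR10 build were used, with no role or order stated. The HTSeq version and mode, the use of strand and the annotation release were not given in the sources used here. Of the entries, 32679 name a gene or VP16 and 5 name none. The latter were left out of library sizes and tests. Reads on no feature made up 0.76 to 1.94% and ambiguous reads 1.32 to 1.48% of a library. The reference used here is TAIR10.1, whose name differs from the authors' build. It served for gene names, products and the order of neighbouring genes, and no coordinates are given. In it 31912 loci were matched and 10616 had a symbol other than the locus code. An entry named VP16 belongs to no locus of the reference and was kept as a gene.

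Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the groups with a minimum count of 10, which left 19566. Library sizes were scaled with TMM, and a quasi-likelihood model was fitted to all 30 libraries, so that every group shared 1 estimate of the spread. The common biological coefficient of variation was 0.13. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Where a number of genes at an unadjusted p under 0.05 is given, unchanged genes alone would give a share of about 0.05 of the 19566. Where an SE follows a log2 fold change it is its standard error. CPM values were scaled with TMM, and an SD beside a mean CPM is that over 3 libraries. Gene lists were tested with camera of limma 3.58.1 on voom log2 CPM, with a preset correlation of 0.01 between genes and adjustment over all lists and comparisons together. Each list was also tested with a correlation estimated from the data, and no list call held with it. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

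Depth ranged from 10076308 to 40780331 reads on genes, with a median of 19024898. Between replicates of a group the chi-square of the counts per degree of freedom was 3.54 to 59.39, above sampling noise in every pair, and no pair of libraries was identical. Nothing in the labels says that the replicates came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical. The replicate letters A, B and C recur in every group. Deviations from the group means were correlated by more than 0.1 for every pair of like-lettered libraries only between the EAR pool 15 background and Col-0, at 0.28, 0.21 and 0.15. For that comparison alone the letters were read as a possible pairing of samples. With the letter as a block that comparison called 1282 genes in place of 1293. The block was fitted over all 30 libraries, so a letter had the same effect in every group. What a pairing within these groups alone would change was not tested. The main values given for this comparison come from the model without the block. The pairing comes from the data and not from a label.

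Each of the 5 lines was compared with its pool background, EAR-15-025 with EAR-15-053, and each of the 4 pool backgrounds with Col-0. Differences between line effects were tested as interaction contrasts for the 10 pairs of lines. For EAR-15-025 and EAR-15-053, which share a pool, the pool cancels and this contrast is the same test as their direct comparison. The groups, comparisons, tests, 20 gene lists, naming rule and most alternatives were fixed before the data were examined. The lists, written from textbook knowledge, were light harvesting and Rubisco small subunit, circadian clock, cell cycle and DNA replication, cell wall loosening, auxin response, gibberellin and brassinosteroid metabolism, cytosolic ribosomal proteins, salicylic acid defence, jasmonate response, cold, drought and abscisic acid response, aliphatic glucosinolate synthesis, flavonoid and anthocyanin synthesis, iron status, phosphate starvation, senescence and carbon starvation, heat shock and chaperones, touch, wounding and handling response, flowering and floral identity, root markers and seed storage markers. None of the seed storage genes passed the count filter, so 19 lists were tested. For a line against its pool, the genes named are the 10 highest and 10 lowest log2 fold changes among called genes with a symbol, a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups, and the 2 highest and 2 lowest without the symbol condition. For the other comparisons the numbers are 5 and 5, and 1 and 1. Chance gives no overlap for 10% of genes with 3 libraries against 3. Up to 4 members of each list with the smallest adjusted p may be named as well. Named genes whose function is not well known may be left out of the prose.

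Alternatives were edgeR's RLE size factors or library size alone in place of TMM, no count filter, the test of DESeq2 1.42.0, a fit to the 6 libraries of a comparison alone, the replicate letter as a block, a 2-fold minimum, no organelle genes, Col-0 as the control of the lines, and each library left out in turn. A fit without 4 libraries picked by eye as standing apart from their groups, a fit without 4 libraries apart by a rule on the chi-square, and the alternatives for interaction contrasts, were added after seeing the data. Leaving out the libraries least like their groups lowers the estimated spread by construction, and the chi-square rises with depth. The model was tested on simulated counts with 200 genes changed by known amounts. For EAR-13-068 against its pool, run on 19422 genes, it recovered 44.8% of 1.5-fold, 80.6% of 2-fold and 93.9% of 4-fold changes. For VP16-05-014 against its pool, on 19438 genes, these shares were 44.8%, 76.1% and 93.9%. In a simulated VP16-02-003 comparison in which the auxin list alone was raised, 1 of 19 lists was called, and it was the auxin list. The simulated genes were drawn independently of each other, so this gives no rate of false list calls for correlated genes.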

Results

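Transcript levels were measured by RNA sequencing in shoots of 5 Arabidopsis lines, 4 pool backgrounds and the Col-0 accession, with 3 libraries each. Replicates A, B and C of EAR-13-068 held 28815395, 29209767 and 18884240 reads on genes. Those of EAR-15-025 held 19954571, 16389284 and 18392776, and those of EAR-15-053 21120959, 21795629 and 24142353. The EAR pool 13 background had 37499684, 37076564 and 29262808 and the EAR pool 15 background 18725935, 18668540 and 18339126. VP16-02-003 had 12161681, 13355417 and 12773179 and VP16-05-014 12940337, 12021299 and 15681337. The VP16 pool 2 background had 27396451, 35316482 and 21302302 and the VP16 pool 5 background 12929978, 10637917 and 29125793. Col-0 had 40780331, 10076308 and 19165556. Between 21329 and 23131 genes had a read in a library, the 10 most abundant genes took 8.88 to 12.18% of reads, and plastid genes 0.084 to 1.287%. The first principal components held 30%, 14.1% and 8.9% of the variance. EAR-13-068 C, EAR-15-025 A, EAR-15-053 C and VP16-05-014 C were picked by eye, after seeing the data, as libraries standing apart from the rest of their groups. VP16-05-014 C had a first component of -50.6 beside 24.5 and 26.7 in A and B, and -47, -34.8 and -24.7 in the VP16 pool 5 background. EAR-13-068 C was less clearly apart, with second components of -30.4, -13.1 and 4.7 in A, B and C. By a rule set later, a chi-square to each other library of the group at least 2 times that between the others, EAR-15-025 A, EAR-15-053 C, VP16-05-014 C and VP16 pool 2 C were apart. The plastid share was highest in VP16-05-014 B at 1.287%, Col-0 A at 0.643%, Col-0 B at 0.568% and VP16-05-014 A at 0.564%. Of 83 named genes with a known position, 16 overlap another annotated gene, and since no strand setting is given their reads cannot be told apart from those of the partner. They are UPM1, BES1, BRL3, AT2G05914, FBA5, AT1G66100, XTH15, ORP1A, APR3, APR1, MLO3, ORA47, BT5, AT3G41979, FKF1 and RLP23.

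The count tables hold an entry named VP16, and the sequence behind it was not given in the sources used here. It stood at 8.92 ± 1.26 CPM in VP16-02-003 and 23.6 ± 2.59 CPM in VP16-05-014 (SD, n = 3 each), and at 8.81 ± 2.34 and 12.8 ± 3.48 CPM in the pool 2 and pool 5 backgrounds. In Col-0 it had 3 reads in all 3 libraries together, a mean of 0.0434 ± 0.0549 CPM. The EAR groups also had reads on this entry, with 0.79 ± 0.419 CPM in EAR-13-068, 2.68 ± 1.84 in the EAR pool 13 background, 2.22 ± 0.894 in the EAR pool 15 background, 5.48 ± 0.867 in EAR-15-025 and 7.46 ± 1.51 in EAR-15-053. All 4 pool backgrounds differed from Col-0 in this entry by edgeR's quasi-likelihood test, with adjusted p of 4.28e-05 and 0.00041 for the EAR pools 13 and 15, and 1.26e-06 and 3.38e-07 for the VP16 pools 2 and 5. None of the 5 lines differed from its own pool in it, the smallest adjusted p being 0.0881 for EAR-13-068.

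**Figure D1:**
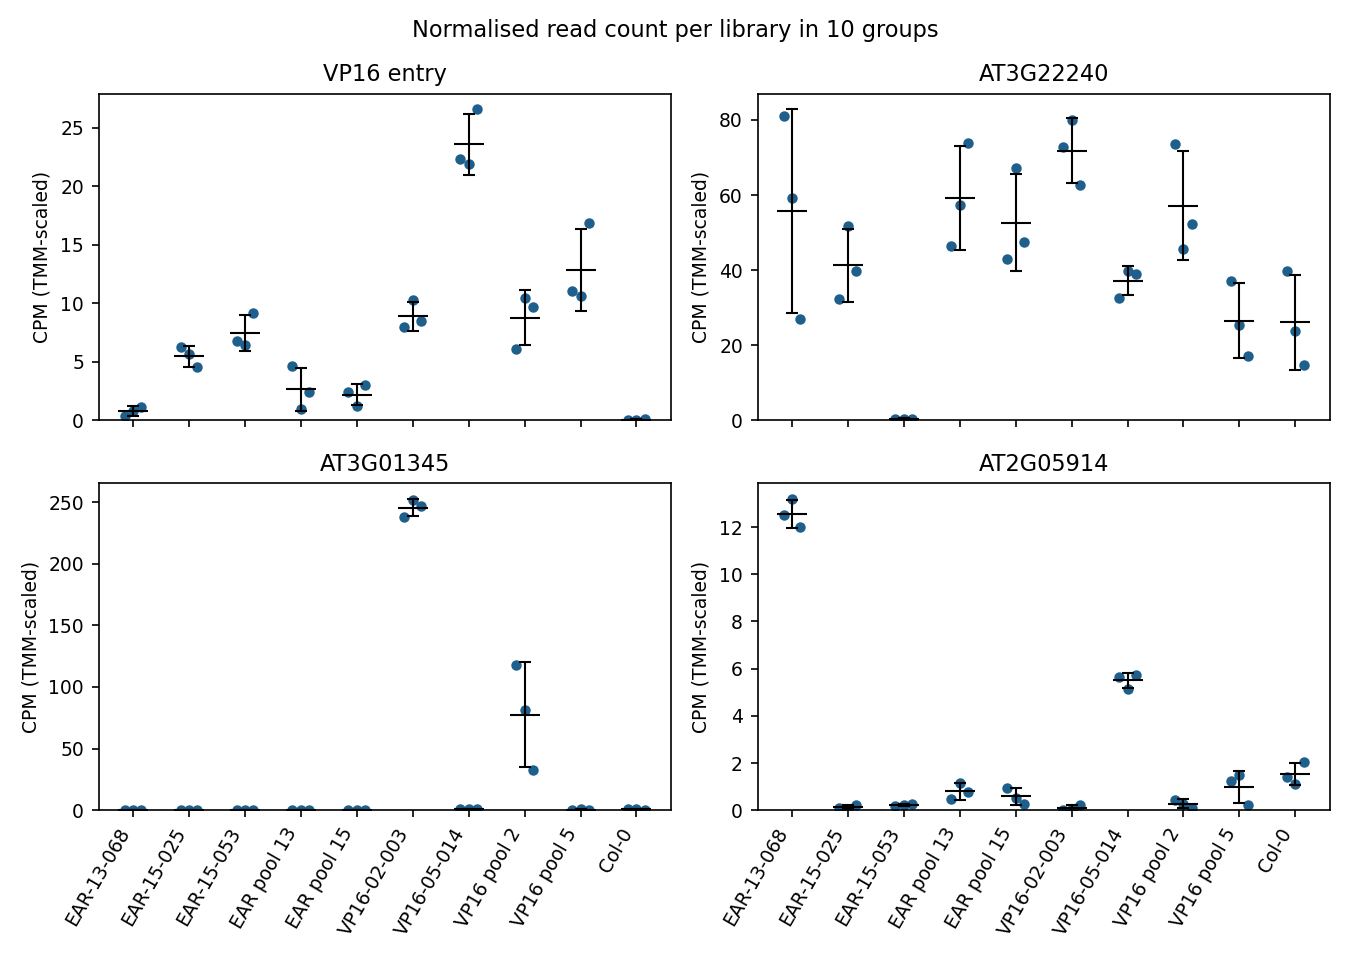
Normalised read count (CPM, TMM-scaled, linear axis from 0) of the VP16 entry and the genes AT3G22240, AT3G01345 and AT2G05914 in each library of the 10 groups; points are libraries, bars the mean ± SD of 3. AT3G22240 stands at 0.461 CPM in EAR-15-053, AT3G01345 at 246 CPM in VP16-02-003 and AT2G05914 at 12.6 CPM in EAR-13-068.

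EAR-13-068 was compared with the EAR pool 13 background for the transcripts that set the selected line apart from its pool. The noncoding RNA AT2G05914, which lies antisense to AT2G05915, stood at 12.6 ± 0.587 CPM in the line and 0.796 ± 0.351 CPM in the pool (SD, n = 3 each), a log2 fold change of 3.98 (SE 0.36, adjusted p = 1.35e-06 by edgeR's quasi-likelihood test). TCP1, a transcription factor of the TCP family, rose by 1.36 on the log2 scale (SE 0.21, adjusted p = 0.0028). UPM1, an enzyme of siroheme synthesis, rose by 0.90 (SE 0.11, adjusted p = 0.000213), from 93.2 ± 6.57 to 174 ± 8.93 CPM, and NIR1, the nitrite reductase that holds siroheme, by 0.62 (SE 0.11, adjusted p = 0.0108). GH9B13, a glycosyl hydrolase of the cellulase family, fell by 1.18 (SE 0.16, adjusted p = 0.000894), from 40.6 ± 2.13 CPM in the pool. The chitinase-family gene AT2G43590 changed by -1.54 (SE 0.23, adjusted p = 0.0028) and GRP9, a glycine-rich protein, by -2.45 (SE 0.41, adjusted p = 0.0107). Also higher were the xyloglucan endotransglucosylase XTH8, the auxin-response repressor AXR3, the peptide RGF9, the vacuolar invertase ATBETAFRUCT4, TBL45, the tocopherol cyclase VTE1 and the brassinosteroid transcription factor BES1, with log2 fold changes from 0.32 to 0.78. Lower were TBL36, the brassinosteroid receptor-like BRL3, the extensin EXT4, the jasmonate methyltransferase JMT and the cellulase-family GH9B1, from -0.97 to -0.61. AT2G05914, TCP1, UPM1 and GH9B13 passed in all 6 fits that left out 1 library. The other 15 of the 19 named genes lost the call in at least 1, with adjusted p up to 0.385. The losses were 15 without EAR-13-068 B, 14 without pool 13 A, 13 without EAR-13-068 C, 11 without pool 13 C, 9 without pool 13 B and 6 without EAR-13-068 A.

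In EAR-13-068 8 of the 19 gene lists passed limma's camera, 3 of them in each fit that left out 1 library. The salicylic acid defence genes were lower as a list, with a median log2 fold change of -0.68 over 25 genes (adjusted p = 1.08e-09, and adjusted p = 0.509 with an estimated correlation). No member passed edgeR's test over all genes or adjusted over the list alone. At an unadjusted p under 0.05 13 were lower, and DESeq2 called 0. PR1, a pathogenesis-related marker of this response, had a log2 fold change of -1.60 (adjusted p = 0.288) and ICS1, the enzyme of salicylate synthesis, -0.74 (adjusted p = 0.167). The pool was itself higher than Col-0 in this list, as given below, so part of the lower value may come from the pool. The aliphatic glucosinolate list was higher, with a median of 0.54 over 18 genes (adjusted p = 2.71e-07, and adjusted p = 0.67 with an estimated correlation). Again no member passed over all genes or adjusted over the list alone, with 5 higher at an unadjusted p under 0.05 and 0 called by DESeq2. The iron status list was higher, with a median of 0.29 over 14 genes (adjusted p = 0.000304, and adjusted p = 0.497 with an estimated correlation). Of its genes 2 were higher over all genes and, adjusted over the list alone, 5 higher and 1 lower. They were the iron-deficiency transcription factors BHLH38 at 3.09 (SE 0.6, adjusted p = 0.0369) and BHLH100 at 3.02 (SE 0.58, adjusted p = 0.0369), the latter below 1 CPM in both groups. Both lost the call without EAR-13-068 B (adjusted p = 0.0587 and 0.0853), EAR-13-068 C (0.153 and 0.149), pool 13 A (0.0856 and 0.107) or pool 13 B (0.0957 each), and BHLH38 also without pool 13 C (0.162). In all, 46 of 19566 genes were called in this comparison, 23 higher and 23 lower, 21 of them at least 2-fold. The pool enters this comparison and that of the pool with Col-0 with opposite sign. Of the 46 genes 13 were called in the opposite direction in pool 13 against Col-0, 1 was higher in both and 0 lower in both. With Col-0 as the control in place of the pool, 19 of the 46 were called as well. There were 2152 genes that had an unadjusted p under 0.05. With scaling by library size alone the split was 11 higher and 43 lower, and DESeq2 called 151, 81 higher and 70 lower. Leaving out 1 library gave 4 genes without EAR-13-068 B, 6 without pool 13 A, 13 without EAR-13-068 C, 15 without pool 13 C and 19 without pool 13 B. Without the 4 libraries standing apart 295 were called, 182 higher and 113 lower, and 605 without those apart by chi-square, 388 and 217.

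EAR-15-025 was compared with the EAR pool 15 background in the same way. The ferric reductases FRO7 and FRO6 were higher, with log2 fold changes of 0.94 (SE 0.18, adjusted p = 0.0465) and 0.89 (SE 0.15, adjusted p = 0.0207 by edgeR), FRO6 at 280 ± 34.2 CPM in the line and 150 ± 19.8 CPM in the pool (SD, n = 3 each). FBA5, a fructose-bisphosphate aldolase, was at 0.69 (SE 0.13, adjusted p = 0.0465), NCED4, a carotenoid cleavage enzyme, at 0.62 (SE 0.12, adjusted p = 0.0465), and CYSD2, a cysteine synthase, at 0.51 (SE 0.09, adjusted p = 0.0465). CVL1 and CYP71B4 were higher too. The thionin gene AT1G66100 was lower, at 48.9 ± 6.57 against 94.9 ± 9.44 CPM (log2 fold change -0.96, SE 0.15, adjusted p = 0.0097). In all, 10 genes were called, 8 higher and 2 lower, with 1729 at an unadjusted p under 0.05 and 139 called by DESeq2, 135 higher and 4 lower. Scaling by library size alone gave 1 higher and 2 lower. The replicate letter as a block gave 4 genes, 2 higher and 2 lower, all among the 10. FRO6, NCED4 and AT1G66100 were in it, while FRO7, FBA5, CVL1, CYP71B4 and CYSD2 lost the call, with adjusted p of 0.0531 to 0.0723. The 2 genes outside the naming rule, AT3G14067, a subtilase, at 0.50 and AT5G64980 at -1.07, were named after their values were seen. None of the 8 named genes held the call in every fit that left out 1 library, with adjusted p up to 0.454. The count was 0 without EAR-15-025 A, 1 without EAR-15-025 B or pool 15 B, 2 without pool 15 C, 3 without EAR-15-025 C and 4 without pool 15 A. All 8 calls were lost without EAR-15-025 A, EAR-15-025 B or pool 15 B, 7 without pool 15 C, and 6 without pool 15 A or EAR-15-025 C. Without the 4 libraries standing apart 8 genes were called. Of the 19 lists 5 passed camera, and the light harvesting and Rubisco list did so in every fit that left out 1 library. It was higher by a median of 0.29 over 22 genes (adjusted p = 9.34e-18, and adjusted p = 0.497 with an estimated correlation). No member passed over all genes, where 19 were higher at an unadjusted p under 0.05 and DESeq2 called 5 higher, and 19 were higher adjusted over the list alone. LHCA1, an antenna protein of photosystem I, had a log2 fold change of 0.36 (SE 0.1, adjusted p = 0.226).

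EAR-15-053 differed from the EAR pool 15 background in 1 gene by edgeR's test. AT3G22240, which encodes a cysteine-rich transmembrane protein related to PCC1, was at 0.461 ± 0.0778 CPM in the line and 52.6 ± 12.9 CPM in the pool (SD, n = 3 each), a log2 fold change of -6.81 (SE 0.51, adjusted p = 2.52e-08). It was lower in all 3 libraries than in any of the other 27, where group means ran from 26.1 CPM in Col-0 to 71.9 CPM in VP16-02-003. Its relatives PCC1 and AT3G22235 lie next to it, so reads shared between them leave its level uncertain. The call passed in all 15 alternatives, with adjusted p up to 2.88e-06 when 1 library was left out. At an unadjusted p under 0.05 there were 1133 genes, DESeq2 called 17, and leaving out pool 15 A, the 4 libraries standing apart or those apart by chi-square gave 2. Unchanged genes alone would give a share of about 0.05 of the 19566 tested, so most of the 1133 may be chance. Of the 19 lists 6 passed camera, and the cytosolic ribosomal protein list did so in every fit that left out 1 library. Its median was -0.11 over 21 genes (adjusted p = 7.94e-07, and adjusted p = 0.67 with an estimated correlation). No ribosomal gene passed over all genes or adjusted over the list alone, 3 were lower at an unadjusted p under 0.05, and DESeq2 called 0. RPL8A had a log2 fold change of -0.20 (SE 0.07, adjusted p = 0.82).

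The pair of lines from EAR pool 15 was set against each other for differences between lines of the same pool and fusion. AT3G22240 was at 41.3 ± 9.77 CPM in EAR-15-025 and 0.461 ± 0.0778 CPM in EAR-15-053 (SD, n = 3 each), a log2 fold change of 6.46 (SE 0.51, adjusted p = 8.21e-08 by edgeR). The thionin gene AT1G66100 was lower in EAR-15-025, at 48.9 ± 6.57 against 109 ± 17.2 CPM (log2 fold change -1.16, SE 0.15, adjusted p = 0.000406). With AT5G64980, named after its values were seen, at -1.09 (adjusted p = 0.000459), 3 genes were called, and both named genes passed in every fit that left out 1 library. There were 1900 genes at an unadjusted p under 0.05, DESeq2 called 29, and library size alone gave 5, 1 higher and 4 lower. A fit to the 6 libraries alone gave 1 and lost AT1G66100, and the fits without the libraries standing apart and without those apart by chi-square gave 11 and 6. Of the 4 lists that passed camera, light harvesting and salicylic acid defence did so in every such fit. Light harvesting genes were higher in EAR-15-025, with a median of 0.26 over 22 genes (adjusted p = 1.72e-10, and adjusted p = 0.509 with an estimated correlation). None passed over all genes, 13 were higher at an unadjusted p under 0.05, DESeq2 called 0, and adjusted over the list alone 7 were higher. Salicylic acid defence genes were lower, with a median of -0.72 over 25 genes (adjusted p = 2.11e-07, and adjusted p = 0.66 with an estimated correlation). None passed over all genes, 6 were lower at an unadjusted p under 0.05, DESeq2 called 0, and adjusted over the list alone 2 were lower.

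VP16-02-003 differed from the VP16 pool 2 background in 5694 of 19566 genes by edgeR's test, 29.1% of those tested. Among the lowest were the adenylylsulfate reductases APR1 at 25.3 ± 6.14 against 274 ± 57.1 CPM (SD, n = 3 each; log2 fold change -3.44, SE 0.58, adjusted p = 0.000237) and APR3 at 19.8 ± 4.04 against 236 ± 66.7 CPM (-3.57, SE 0.61, adjusted p = 0.000261). The low-sulfur response genes LSU3, LSU2 and ATSDI1 changed by -4.17 (SE 0.93, adjusted p = 0.00234), -3.91 (SE 0.93, adjusted p = 0.00359) and -3.26 (SE 0.79, adjusted p = 0.00421). Among the highest, YUC9, an enzyme of auxin synthesis, was at 7.68 ± 1.79 against 0.712 ± 0.563 CPM (3.49, SE 0.66, adjusted p = 0.000571), the expansin EXPA16 at 17.9 ± 4.07 against 2.55 ± 0.697 CPM (2.84, SE 0.42, adjusted p = 6.63e-05), and XTH15, which remodels xyloglucan, at 3.26 (SE 0.28, adjusted p = 3.27e-08). The smallest adjusted p among the named genes was that of AT1G20490, of the AMP-dependent synthetase family, at 35 ± 1.41 against 3.07 ± 0.163 CPM (3.51, SE 0.18, adjusted p = 1.35e-12). GSTU26, a glutathione transferase, was at 25.8 ± 0.529 against 6.02 ± 0.684 CPM (adjusted p = 2.18e-11). GAD, a glutamate decarboxylase, was at 2.12 (SE 0.21, adjusted p = 4.23e-07), and the auxin-response gene IAA29 at 2.02 (SE 0.59, adjusted p = 0.0138). The zinc-finger gene ZAT11 was at -3.72 (SE 0.58, adjusted p = 0.000105), the vegetative storage protein gene VSP1 at -3.49 (SE 0.83, adjusted p = 0.0038), and CYP79F2, of aliphatic glucosinolate synthesis, at -3.08 (SE 0.56, adjusted p = 0.000414). Of the 21 named genes 19 passed in every fit that left out 1 library. The chitinase gene CHI (AT2G43570) at 2.03 lost the call without VP16-02-003 B (adjusted p = 0.327), pool 2 B (0.141) or pool 2 C (0.116), and PAP1, a regulator of anthocyanin synthesis, at -3.20 without VP16-02-003 B (0.0753) or C (0.0656).

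The calls divided into 2987 higher and 2707 lower, 510 and 699 of them at least 2-fold, and into 3638 higher and 2017 lower with scaling by library size alone. Lower genes were the more numerous without organelle genes, at 2629 higher and 3043 lower, without the count filter, at 2435 and 2682, and with the 6 libraries alone, at 2736 and 2780. This was so too without pool 2 B, at 1802 and 2261, and without pool 2 C, at 2190 and 2589, so the balance depends on these settings. The lowest count with 1 library left out was 3756, without VP16-02-003 B. The plastid share was 0.222, 0.247 and 0.403% in VP16-02-003 A, B and C and 0.132, 0.131 and 0.382% in the pool. Of the 19 lists 8 passed camera, 7 of them in every fit that left out 1 library. Of the aliphatic glucosinolate genes 17 of 18 fell, and 18 adjusted over the list alone, with a median of -2.06 (adjusted p = 4.89e-13, and adjusted p = 0.509 with an estimated correlation). BCAT4 and MAM1, of methionine chain elongation, were at 49.6 against 211 CPM (-2.09, SE 0.33, adjusted p = 0.000138) and 186 against 421 CPM (-1.18, SE 0.19, adjusted p = 0.000152). Of the flavonoid and anthocyanin genes 11 of 15 fell, and 11 adjusted over the list alone, with a median of -2.19 (adjusted p = 2.02e-05, and adjusted p = 0.67 with an estimated correlation), LDOX at -2.36 (SE 0.37, adjusted p = 0.000132) and DFR at -1.64 (SE 0.28, adjusted p = 0.000228) among them. Of the jasmonate response genes 14 of 24 fell, and 14 adjusted over the list alone, with a median of -1.01 (adjusted p = 5.13e-07, and adjusted p = 0.509 with an estimated correlation). The lipoxygenases LOX4 and LOX2 were at -2.08 (SE 0.28, adjusted p = 2.19e-05) and -1.35 (SE 0.21, adjusted p = 0.000126), LOX2 at 363 against 927 CPM. Touch, wounding and handling genes fell in 10 of 16 cases, and in 13 adjusted over the list alone, with a median of -1.57 (adjusted p = 3.17e-06, and adjusted p = 0.509 with an estimated correlation). The ethylene-response factors ERF5 and ERF6 were at -2.18 (SE 0.42, adjusted p = 0.000759) and -2.19 (SE 0.35, adjusted p = 0.000148). The pool was itself higher than Col-0 in the touch list, as given below, so part of this fall may come from the pool. Of the iron status genes 8 of 14 fell, and 8 adjusted over the list alone, with a median of -0.61 (adjusted p = 0.00353, and adjusted p = 0.509 with an estimated correlation), IMA1, an iron-uptake peptide, at -1.85 (SE 0.39, adjusted p = 0.00142).

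Auxin response genes rose in 9 of 20 cases in VP16-02-003, and in 12 adjusted over the list alone, with a median of 0.70 (adjusted p = 0.000165, and adjusted p = 0.681 with an estimated correlation). IAA19 was at 1.49 (SE 0.26, adjusted p = 0.000274), SAUR19 at 1.14 (SE 0.26, adjusted p = 0.00253) and the auxin carrier gene PIN3 at 0.65 (SE 0.15, adjusted p = 0.00253). Cytosolic ribosomal protein genes were lower in 6 of 21 cases, and in 11 adjusted over the list alone, with a median of -0.15 (adjusted p = 0.00094, and adjusted p = 0.764 with an estimated correlation). Cell cycle genes were lower in 4 of 32 cases, and in 2 adjusted over the list alone, with a median of -0.18 (adjusted p = 0.0295, and adjusted p = 0.79 with an estimated correlation). That call was lost without VP16-02-003 A (adjusted p = 0.0524), VP16-02-003 C (0.057) or pool 2 C (0.173). The other 11 lists missed the threshold. Of all 19566 genes 29.1% were called in VP16-02-003, so calls within a list do not by themselves set it apart. Clock genes were 4 higher and 7 lower of 28, likewise adjusted over the list alone (camera adjusted p = 0.287), with LHY at 1.47 (SE 0.27, adjusted p = 0.000444) and ELF4 at -1.98 (SE 0.42, adjusted p = 0.0014). Cell wall loosening genes were 4 higher and 7 lower of 21, and 4 and 11 adjusted over the list alone (camera adjusted p = 0.126), with the expansin gene EXPA8 at -1.36 (SE 0.24, adjusted p = 0.000309). Cold, drought and abscisic acid genes were 5 higher and 10 lower of 28, and 6 and 13 adjusted over the list alone (camera adjusted p = 0.0711), with COR15B at -1.74 (SE 0.29, adjusted p = 0.000181). Gibberellin and brassinosteroid genes were 4 higher and 1 lower of 13, likewise adjusted over the list alone, with a median of -0.02 but a mean of 0.18 and a test directed upwards (camera adjusted p = 0.313), and BR6OX2, of brassinosteroid synthesis, at 1.78 (SE 0.21, adjusted p = 3.85e-06).

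Salicylic acid defence genes in VP16-02-003 were 4 higher and 1 lower of 25, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.134), with WRKY70, a transcription factor of this response, at -1.47 (SE 0.32, adjusted p = 0.00212). Flowering genes were 3 higher and 0 lower of 8, and 3 and 1 adjusted over the list alone (camera adjusted p = 0.266), with the floral promoters FUL at 1.65 (SE 0.33, adjusted p = 0.00097) and SOC1 at 0.76 (SE 0.17, adjusted p = 0.00273). Phosphate starvation genes were 3 lower of 8, also adjusted over the list alone (camera adjusted p = 0.192). Heat shock genes were 4 lower of 12, also adjusted over the list alone (0.153), and light harvesting genes 1 lower of 22, also adjusted over the list alone (0.407). Senescence genes were 1 higher and 2 lower of 17, and 1 and 1 adjusted over the list alone (camera adjusted p = 0.586), with NYC1, of chlorophyll breakdown, at -0.57 (SE 0.07, adjusted p = 3.96e-06). Of the 4 root markers 0 passed edgeR's test or the test adjusted over the list alone, 0 had an unadjusted p under 0.05 and DESeq2 called 0 (camera adjusted p = 0.604).

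VP16-05-014 was compared with the VP16 pool 5 background, whose line libraries had the largest chi-square per degree of freedom between replicates, 59.39. The phytochrome kinase substrate gene PKS2 was higher, at 44.2 ± 9.96 CPM in the line (SD, n = 3) and a log2 fold change of 1.31 (SE 0.19, adjusted p = 0.00519 by edgeR). AT2G05914 stood at 5.5 ± 0.329 against 0.968 ± 0.673 CPM (2.79, SE 0.43, adjusted p = 0.00907). These 2 of the 22 named genes passed in every fit that left out 1 library. LOX4, of jasmonate synthesis, was lower at 9.03 ± 1.89 against 31.7 ± 7.65 CPM (-1.81, SE 0.28, adjusted p = 0.00907), ORA47, an ethylene-response-factor gene, was at -2.93 (SE 0.49, adjusted p = 0.0114), and DIC2, a mitochondrial dicarboxylate carrier, at -2.76 (SE 0.51, adjusted p = 0.0134). WAK1, a wall-associated kinase, was at 1.59 (SE 0.38, adjusted p = 0.0402) and XTH24 at 1.09 (SE 0.22, adjusted p = 0.0172). GH3.3, which conjugates auxin, was at 15.2 ± 6.85 against 6.05 ± 0.599 CPM (adjusted p = 0.0411). The ribosomal RNA gene AT3G41979 was higher (adjusted p = 0.0171), with 78.4, 165 and 22 CPM in VP16-05-014 A, B and C and 19.1 ± 1.39 CPM in the pool. The 20 others lost the call at least once, with adjusted p up to 0.245. The losses were 20 without pool 5 B, 19 without VP16-05-014 B, 16 without pool 5 C, 14 without VP16-05-014 A and 9 without pool 5 A. In all, 293 genes were called, 124 higher and 169 lower, with 3871 at an unadjusted p under 0.05. These compare with 68 higher and 161 lower with library size alone, and the balance turned with DESeq2, at 435 higher and 308 lower of 743. It turned too without VP16-05-014 C, at 2611 and 2464, without pool 5 B, at 2 and 0, and in the fits without 4 libraries, at 3082 and 2645 and at 3207 and 2856. A fit to the 6 libraries alone called 0 and lost all 22 named genes. The count was 5075 without VP16-05-014 C, 64 without A, 21 without B, 2 without pool 5 B, 60 without pool 5 C and 124 without pool 5 A. It was 5727 without the 4 libraries standing apart and 6063 without those apart by chi-square.

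Among the gene lists in VP16-05-014, 7 of 19 passed camera, 3 of them in every fit that left out 1 library. Cell cycle and DNA replication genes were lower, with 3 of 32 past the test over all genes and 15 adjusted over the list alone, and a median of -0.33 (adjusted p = 4.89e-13, and adjusted p = 0.497 with an estimated correlation). CDC20.2, an activator of mitotic proteolysis, was at -0.63 (SE 0.13, adjusted p = 0.0202). Touch, wounding and handling genes were lower in 5 of 16 cases, and in 10 adjusted over the list alone, with a median of -1.03 (adjusted p = 5.74e-07, and adjusted p = 0.497 with an estimated correlation), ERF6 at -1.75 (SE 0.36, adjusted p = 0.0191) and SZF1, a zinc-finger protein gene, at -2.05 (SE 0.43, adjusted p = 0.0205). Auxin response genes were higher in 4 of 20 cases, and in 11 adjusted over the list alone, with a median of 0.66 (adjusted p = 2.7e-06, and adjusted p = 0.577 with an estimated correlation), PIN3 at 0.63 (SE 0.15, adjusted p = 0.0339) among them. For flavonoid genes the median of 0.15 and the mean of 0.12 were above 0 while the test was directed downwards (camera adjusted p = 0.962). Within VP16-05-014, C differed from A and B in several of these lists and in measures of the libraries. The plastid share was 0.564 and 1.287% in A and B, 0.147% in C and 0.13 to 0.227% in the pool, and reads on no feature were 1.24, 1.94 and 0.84% in A, B and C and 0.81 to 0.94% in the pool. The glucosinolate genes of C were above the mean of A and B by a median of 1.84 on the log2 scale, in 18 of 18 genes, its flavonoid genes by 1.78, in 15 of 15, and its auxin genes were at -0.96. CDC20.2 and PIN3 lost the call without VP16-05-014 A (adjusted p = 0.126 and 0.174), VP16-05-014 B (0.064 and 0.195), pool 5 A (0.0577 and 0.118), pool 5 B (0.0811 and 0.123) or pool 5 C (0.0738 and 0.065). ERF6 and SZF1 lost it without VP16-05-014 B (adjusted p = 0.0782 and 0.0822) or pool 5 B (0.0984 and 0.111), and ERF6 also without pool 5 C (0.0601).

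**Figure D2:**
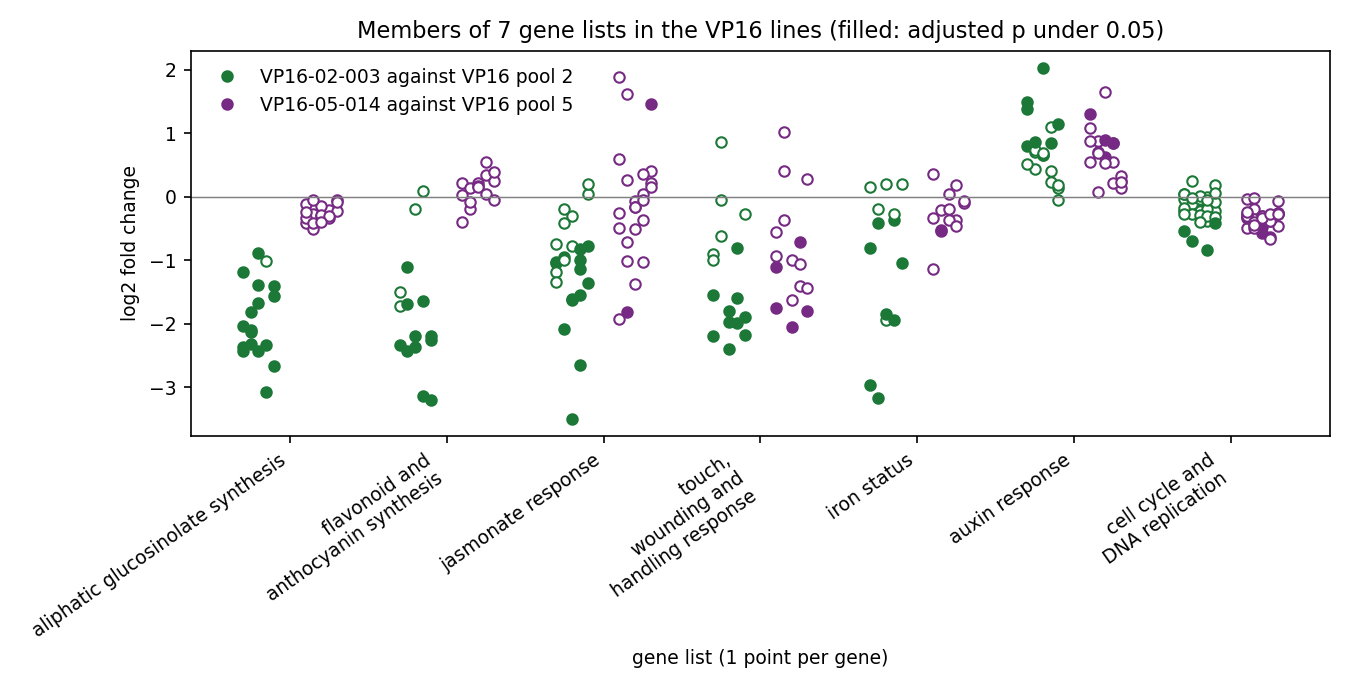
Log2 fold change (vertical axis) of the members of 7 gene lists in VP16-02-003 against the pool 2 background and VP16-05-014 against the pool 5 background; each point is 1 gene, filled where the adjusted p was under 0.05. In VP16-02-003 17 of 18 glucosinolate genes are filled and below 0, and 9 of 20 auxin genes filled and above 0.

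The EAR pool backgrounds were compared with Col-0, whose label names no fusion, and circadian clock genes were among the lowest in both. FKF1, a light-sensing F-box protein of the evening, was at 0.539 ± 0.227 CPM in pool 13 and 22.3 ± 3.12 CPM in Col-0 (SD, n = 3 each; log2 fold change -5.40, SE 0.45, adjusted p = 1.17e-07 by edgeR), and at -3.40 (SE 0.4, adjusted p = 2.18e-05) in pool 15. The pseudo-response regulator PRR3 was at -3.58 (SE 0.32, adjusted p = 2.52e-07) and -2.75 (SE 0.32, adjusted p = 2.18e-05), and the cold- and clock-regulated COR27 at -5.64 (SE 0.67, adjusted p = 7.18e-06) and -4.05 (SE 0.63, adjusted p = 0.000381). LHY, a morning clock transcription factor, was higher in the pools at 2.51 (SE 0.28, adjusted p = 2.67e-06) and 2.07 (SE 0.28, adjusted p = 8.78e-05). Of 28 clock genes 8 were higher and 12 lower in pool 13 (12 and 12 adjusted over the list alone), and 5 higher and 10 lower in pool 15 (6 and 11 adjusted over the list alone). The plastid share was 0.643, 0.568 and 0.182% in Col-0 A, B and C, 0.084 to 0.13% in pool 13 and 0.158 to 0.358% in pool 15. Camera, which asks for 1 direction, gave adjusted p of 0.115 and 0.0922. GRP7, a clock-regulated RNA-binding protein, fell in pool 13 from 1220 ± 109 to 172 ± 49.9 CPM (-2.83, SE 0.35, adjusted p = 1.03e-05), and PRR5 from 103 ± 10.1 to 7.39 ± 2.98 CPM (-3.81, SE 0.43, adjusted p = 3.69e-06). The vacuolar cation exchanger gene CAX3 was higher in pool 13 at 3.59 (SE 0.74, adjusted p = 0.00327), and in pool 15 MYB47 was lower at -3.17 (SE 0.39, adjusted p = 3.16e-05), NUDT8 lower at -1.86 (SE 0.21, adjusted p = 2.18e-05) and the receptor kinase gene IOS1 higher at 2.48 (SE 0.52, adjusted p = 0.00592). These genes passed in every fit that left out 1 library, as did 6 of the 11 named genes in each pool. The others, among them BGL2 (PR2) in pool 13 and SAG13 in both, lost the call in at least 1. The adjusted p reached 0.0977 in pool 13, where 5 were lost without pool 13 C and 5 without Col-0 C, 3 without Col-0 A and 2 without Col-0 B. In pool 15 the adjusted p reached 0.245, where 5 were lost without pool 15 B and 3 each without Col-0 A, B or C. In the 5 lines against their own pools the median of the afternoon and evening clock genes minus that of the morning ones ran from -0.78 to -0.52, the genes being sorted by phase after their values were seen. In the EAR pools against Col-0 the afternoon and evening list had p of 0.000265 in pool 13 and 0.00133 in pool 15 with an estimated correlation, and the morning list 0.00984 and 0.0819 (limma's camera, unadjusted). Neither phase list had a p under 0.05 in any line with an estimated correlation (limma's camera, smallest p = 0.0598). In EAR-15-053 the difference rested on C, at -2.82 beside -0.63 and -0.53 in A and B and -1.03 to -0.22 in the pool libraries.

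**Figure D3:**
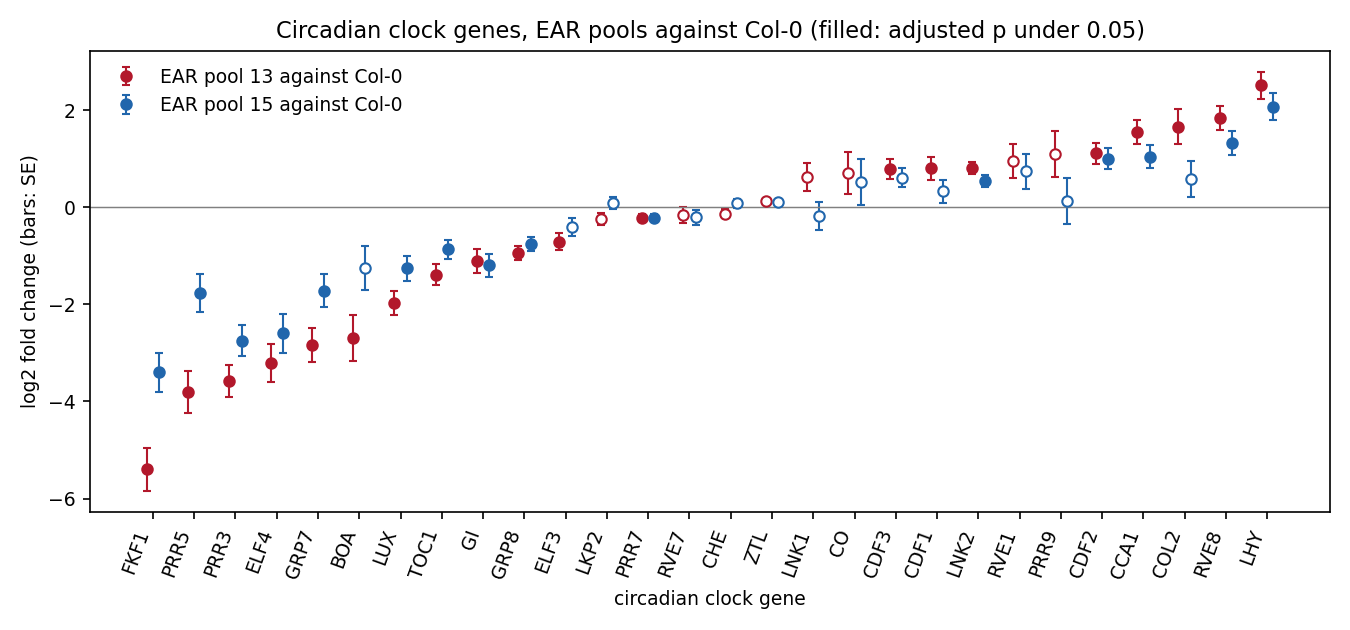
Log2 fold change with its SE (vertical axis) of 28 circadian clock genes in the EAR pool 13 and pool 15 backgrounds against Col-0, ordered by the pool 13 value; points are filled where the adjusted p was under 0.05. FKF1 lies at -5.40 in pool 13 and -3.40 in pool 15, and LHY at 2.51 and 2.07.

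Jasmonate and defence genes also separated the EAR pool backgrounds from Col-0. In pool 13 the jasmonate response genes were lower in 13 of 24 cases (17 lower and 1 higher adjusted over the list alone), with a median of -0.85 (camera adjusted p = 8.03e-09, and adjusted p = 0.497 with an estimated correlation), the repressor gene JAZ9 at -1.32 (SE 0.18, adjusted p = 4.66e-05) and OPR3, of jasmonate synthesis, at -1.68 (SE 0.28, adjusted p = 0.000446). In pool 15 they were lower in 9 of 24 cases (14 lower and 1 higher adjusted over the list alone), with a median of -0.68 (camera adjusted p = 3.17e-06, and adjusted p = 0.509 with an estimated correlation). Salicylic acid defence genes were higher in 14 of 25 cases in pool 13 (17 adjusted over the list alone), with a median of 1.07 (camera adjusted p = 3.76e-08, and adjusted p = 0.618 with an estimated correlation), ICS1 at 1.17 (SE 0.22, adjusted p = 0.00163) among them. In pool 15 they were higher in 6 of 25 cases (10 adjusted over the list alone), with a median of 0.68 (camera adjusted p = 0.000224, and adjusted p = 0.732 with an estimated correlation). Flavonoid genes in pool 13 had a median of 0.70 (camera adjusted p = 0.00118, and adjusted p = 0.732 with an estimated correlation), with 1 of 15 higher, also adjusted over the list alone. Cell cycle genes in pool 15 were lower in 8 of 32 cases (13 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 1.01e-07, and adjusted p = 0.509 with an estimated correlation). These lists passed in every fit that left out 1 library, as 3 of 6 did in pool 13 and 3 of 8 in pool 15. In all, 1705 genes were called in pool 13, 838 higher and 867 lower, and 1293 in pool 15, 650 higher and 643 lower. With library size alone the splits were 1064 to 649 and 830 to 467. The balance was close and turned to more higher genes in pool 13 with the 6 libraries alone, at 1192 to 1092, with a 2-fold minimum, at 299 to 201, without the count filter, at 787 to 717, and without pool 13 A or B, at 515 to 491 and 550 to 518. In pool 15 it turned to more lower genes without organelle genes, at 611 to 736, with RLE size factors, at 628 to 716, with DESeq2, at 788 to 854, and without those apart by chi-square, at 1656 to 1683. It did so too without Col-0 A, B or C, at 308 to 579, 227 to 361 and 290 to 475, and without pool 15 B or C, at 165 to 265 and 446 to 468. In pool 13 the count was 780 without Col-0 B, 887 without pool 13 C, 1006 without pool 13 A, 1068 without pool 13 B and 1097 without Col-0 C. It was 3298 without the libraries standing apart and 3567 without those apart by chi-square. In pool 15 it was 430 without pool 15 B, 588 without Col-0 B, 765 without Col-0 C and 846 without pool 15 A, and 3039 and 3339 in these fits.

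Few genes were called between the VP16 pool backgrounds and Col-0. In pool 2 the VP16 entry was at 7.47 (SE 0.7, adjusted p = 1.26e-06 by edgeR) and in pool 5 at 8.04 (SE 0.68, adjusted p = 3.38e-07), fitted values that are no bound because Col-0 had 3 reads. Pool 2 also had AT3G01345, a glycoside hydrolase-domain protein gene, at 77.4 ± 42.5 CPM against 0.649 ± 0.28 CPM (SD, n = 3 each; log2 fold change 6.97, SE 0.41, adjusted p = 1.1e-10), and AT5G03380, of a metal-binding protein family, at 0.95 (adjusted p = 0.0106), both named after their values were seen. These 3 and 1 genes stand beside 2173 and 1915 at an unadjusted p under 0.05, and 104 and 25 called by DESeq2. Leaving out Col-0 A gave 93 and 25 genes, leaving out VP16 pool 2 C gave 9 and VP16 pool 5 C gave 2. Without the 4 libraries standing apart 819 and 393 were called, and without those apart by chi-square 1972 and 758. The plastid share was 0.643, 0.568 and 0.182% in Col-0 A, B and C, 0.131 to 0.382% in pool 2 and 0.13 to 0.227% in pool 5. In pool 2 9 of 19 lists passed camera, 7 of them in every fit that left out 1 library. Salicylic acid defence genes were higher by a median of 1.13 over 25 genes (adjusted p = 1.91e-10, and adjusted p = 0.509 with an estimated correlation), with 0 past the test over all genes, 19 higher at an unadjusted p under 0.05, 2 by DESeq2 and 18 adjusted over the list alone. WRKY46, a transcription factor of this response, was at 1.75 (adjusted p = 0.11). Touch, wounding and handling genes were higher by a median of 1.02 over 16 genes (adjusted p = 5.74e-07, and adjusted p = 0.497 with an estimated correlation), with 0 past the test over all genes, 10 higher and 2 lower at an unadjusted p under 0.05, 4 and 1 by DESeq2, and 10 and 2 adjusted over the list alone. Jasmonate response genes were lower by a median of -0.45 in pool 2 (adjusted p = 9.87e-07, and adjusted p = 0.509 with an estimated correlation) and -0.39 in pool 5 (adjusted p = 1.98e-06, and adjusted p = 0.509 with an estimated correlation), with 0 of 24 past the test over all genes in either. At an unadjusted p under 0.05 there were 11 lower in pool 2 and, in pool 5, 8 lower and 1 higher. DESeq2 called 5 and 2 lower, and adjusted over the list alone 9 and 7 were lower. Iron status genes in pool 5 were higher by a median of 0.47 over 14 genes (adjusted p = 1.77e-05, and adjusted p = 0.497 with an estimated correlation), with 0 past the test over all genes, 7 higher and 1 lower at an unadjusted p under 0.05, 0 by DESeq2, and 6 and 1 adjusted over the list alone. In pool 5 2 of 6 lists passed in every fit that left out 1 library, jasmonate response and iron status.

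Calls were also compared between contrasts. VP16-02-003 and VP16-05-014, each against its own pool, shared 88 higher genes where independent lists would share 18.93, and 116 lower genes where they would share 23.38, with 5 genes called in opposite directions. Such an excess was not particular to the VP16 lines. With EAR pool 15 against Col-0, VP16-05-014 shared 47 higher genes (4.12 for independent lists) and 57 lower genes (5.55). VP16-02-003 shared 322 higher (99.23) and 334 lower genes (88.96) with that contrast. The calls of VP16-05-014 rested on single libraries, with 2 genes called without pool 5 B and 5075 without VP16-05-014 C. Across genes, which are not independent replicates, the log2 fold changes of the VP16 lines correlated at 0.50, against 0.01 in 5 simulations of unchanged groups. The simulations drew each gene independently, so they hold no variation shared across genes, and the 0.01 is no bound for the 0.50. Other contrasts without a shared group also correlated. EAR-13-068 stood at -0.45 with EAR pool 15 against Col-0 and at -0.36 with VP16-02-003, each line against its pool. The EAR pool 13 and 15 backgrounds, both set against Col-0, shared 350 higher genes (27.84 for independent lists) and 453 lower genes (28.49). Their correlation was 0.81 against 0.52 in simulated unchanged groups with the same controls, and the covariance 0.1538 against 0.0264. EAR-15-025 and EAR-15-053, both set against pool 15, correlated at 0.43, below the 0.51 of unchanged groups, with a covariance of 0.0304 against 0.0278. The 3 Col-0 or pool libraries are too few to be divided between the comparisons, so part of an excess may come from the shared controls.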

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

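The tests of harvest time, of the EAR fusion, of a shared plant state and of foreign reads were chosen only after the results were seen, and the depth test was planned before. Interaction contrasts between line effects, each line taken against its own pool, showed where lines differed (edgeR's quasi-likelihood test, adjusted p under 0.05). VP16-02-003 differed from EAR-13-068 in 4391 genes, from EAR-15-025 in 3266, from EAR-15-053 in 3173 and from VP16-05-014 in 359. VP16-05-014 differed from EAR-13-068 in 233 genes, from EAR-15-025 in 128 and from EAR-15-053 in 40. Among the EAR lines the numbers were 7 for EAR-13-068 and EAR-15-025, 4 for EAR-13-068 and EAR-15-053, and 3 for EAR-15-025 and EAR-15-053. In the last pair the shared pool cancels, so its numbers repeat the direct comparison of these lines. Without the 4 libraries standing apart, an alternative added after seeing the data, the contrasts of VP16-05-014 with EAR-13-068, EAR-15-025 and EAR-15-053 gave 4571, 2576 and 2358 genes. Without the libraries apart by chi-square, added likewise, they gave 5542, 2813 and 2696, and EAR-13-068 with VP16-02-003 gave 6685. Single libraries moved these counts too. With VP16-05-014, EAR-13-068 gave 35 genes without VP16 pool 5 B and 4264 without VP16-05-014 C, EAR-15-025 gave 4 without EAR-15-025 A and 2848 without VP16-05-014 C, EAR-15-053 gave 1 without EAR pool 15 C and 3791 without VP16-05-014 C, and VP16-02-003 gave 153 without VP16-02-003 C and 683 without VP16-05-014 B. With VP16-02-003, EAR-13-068 gave 2757 without EAR pool 13 C, EAR-15-025 1761 without EAR-15-025 A and EAR-15-053 1570 without EAR-15-053 C. Among the EAR lines, EAR-13-068 gave 3 with EAR-15-025 without EAR-13-068 B, and 2 with EAR-15-053 without EAR pool 15 A.

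Some genes were called in opposite directions. TCP1 had a log2 fold change of 1.36 in EAR-13-068 and -0.98 in VP16-02-003 (adjusted p of the difference = 0.000182), the siroheme gene UPM1 0.90 and -0.40 (1.06e-05), the invertase gene ATBETAFRUCT4 0.43 and -0.86 (1.83e-06), and the iron-deficiency gene BHLH100 3.02 and -2.97 (0.000418). The ferric reductase genes FRO7 and FRO6 were at 0.94 and 0.89 in EAR-15-025 and at -1.02 and -0.47 in VP16-02-003 (4.63e-05 and 0.000299). FBA5 was at 0.69 in EAR-15-025, at -0.78 in VP16-02-003 (2.88e-05) and at -0.67 in VP16-05-014 (0.00135). The proline-rich receptor kinase gene PERK4 was named after its values were seen. It was at -1.66 in EAR-13-068, 1.29 in VP16-02-003 and -1.67 in VP16-05-014 (0.000165 and 0.00293 against VP16-02-003). BHLH100 was below 1 CPM in EAR-13-068 and its pool. The calls of ATBETAFRUCT4 and BHLH100 in EAR-13-068 were each lost in at least 1 fit that left out 1 library. So were those of FRO7, FRO6 and FBA5 in EAR-15-025. In all, 15 genes were opposite between EAR-13-068 and VP16-02-003, 6 between EAR-15-025 and VP16-02-003, 5 between VP16-02-003 and VP16-05-014, and 1 between VP16-05-014 and each of EAR-13-068 and EAR-15-025.

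In the EAR pools against Col-0, with clock genes sorted by phase after their values were seen, 12 of the morning had a median log2 fold change of 0.77 and 11 of the afternoon and evening -1.97, a difference of -2.75, and with an estimated correlation the evening list gave p = 0.000265 in pool 13 and 0.00133 in pool 15 and the morning list 0.00984 and 0.0819 (limma's camera, unadjusted). EAR libraries collected earlier in the day would give such a difference, and so would an effect of the lines on the clock, and no harvest time was given in the sources used here. The VP16 pools, whose labels name no EAR fusion, also lay apart from Col-0, at -0.88 in pool 5 and -1.18 in pool 2. All 12 morning genes were higher in both, and 11 of 11 evening genes in pool 2 and 9 of 11 in pool 5 were lower. By library, the mean log2 CPM of evening minus morning genes was 0.27 to 1.24 in the VP16 pools and 1.43 to 1.77 in Col-0. By limma's camera with an estimated correlation the evening list gave p = 0.182 and 0.0206 in pools 5 and 2, and the morning list 0.0792 and 0.0869. The mean of both EAR pools also lay apart from the mean of both VP16 pools, at -1.55. There 9 of 12 morning genes were higher and 11 of 11 evening genes lower. With the p-values of the VP16 pools against Col-0, it cannot be told whether the EAR fusion is the whole cause. The criterion for this was changed 3 times with the values known, from VP16-02-003 against its pool, at -0.78 (adjusted permutation p over genes, which are not independent, = 0.11), to the VP16 pools with a permutation p over genes, to an exact p over libraries whose scores had been seen to part, which shows nothing more than that and is given up, and to a p with an estimated correlation in both VP16 pools. In the other lines against their pools the differences were -0.55 in EAR-13-068 (0.0013), -0.76 in EAR-15-025 (6e-04), -0.61 in EAR-15-053 (6e-04) and -0.52 in VP16-05-014 (0.012, adjusted permutation p over genes), with neither list under 0.05 in any line with an estimated correlation (smallest p = 0.0598), in EAR-15-053 C alone, at -2.82 beside -0.63 and -0.53 in A and B, lay below the pool libraries, at -1.03 to -0.22, and harvest time and group cannot be separated with 3 shared Col-0 libraries.

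VP16-02-003 had 5694 changed genes and libraries of 12161681 to 13355417 reads against 21302302 to 35316482 in its pool. A lower depth is argued against as the cause, since thinning the pool libraries to 12763426 reads left 5216 called genes, 4825 of them among the original calls. A state of the plants that also varies between libraries of 1 group may account for part of the change. The effect correlated across genes at 0.56 with the main axis of variation within the groups of the other 24 libraries, and the shift along it was 41.9, within the largest range inside 1 group, 99.7 in VP16-05-014, while with that group also left out the correlation was 0.58 and the shift 43.6 against 60.4 in EAR-15-053, each range being set by 1 library, C. The axis held 30.7% of the variance of the effect, so the larger part is not covered by it, and an effect of the line itself stays open as untested.

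The VP16 entry had 7.46 ± 1.51 CPM in EAR-15-053, whose labels name no VP16 fusion (SD, n = 3). Reads from VP16 plants or libraries are argued against as the cause. AT3G22240, at most 0.525 CPM in EAR-15-053 and at least 17.2 CPM in every VP16 library, allows a share of foreign reads of at most 3.06%, while the VP16 entry would need at least 24.1%. Construct sequence shared by the EAR and VP16 plants was not tested and stays open, since the sequence behind the entry is not given in the sources used here. No biological explanation was tested.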

How the results depend on the processing

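The fit without the 4 libraries standing apart, that without the libraries apart by chi-square and every alternative for the interaction contrasts were chosen only after seeing the data, and the others were planned before. Counts of called genes stayed within 1.5 times for all 10 comparisons with RLE size factors, without the count filter and without organelle genes. A 2-fold minimum, which removes calls by construction, left 21 genes in EAR-13-068, 1 in EAR-15-025, 1209 in VP16-02-003, 99 in VP16-05-014, 500 in EAR pool 13 and 365 in EAR pool 15. The cause was not tested for the changes that follow. Library size alone gave 3 genes in EAR-15-025, where it moved the median of all genes to -0.102 from -0.021, and 5 between EAR-15-025 and EAR-15-053. DESeq2 called 151 in EAR-13-068, 139 in EAR-15-025, 17 in EAR-15-053, 743 in VP16-05-014, 29 between EAR-15-025 and EAR-15-053, 104 in VP16 pool 2 and 25 in VP16 pool 5. The 6 libraries alone gave 0 in VP16-05-014 and 1 between EAR-15-025 and EAR-15-053. In EAR-13-068 they gave 50 genes, of which 17 were among the 46 of the main fit. In EAR-15-025 they gave 7, of which 4 were among the 10 of the main fit. Against Col-0 in place of the pool, a comparison of other groups, the counts were 1818 in EAR-13-068, 849 in EAR-15-025, 2112 in EAR-15-053 and 103 in VP16-05-014. Without the 4 libraries they were 295 in EAR-13-068, 2 in EAR-15-053, 5727 in VP16-05-014, 11 between EAR-15-025 and EAR-15-053, 3298 in EAR pool 13, 3039 in EAR pool 15, 819 in VP16 pool 2 and 393 in VP16 pool 5. Without the libraries apart by chi-square, in the same order, they were 605, 2, 6063, 6, 3567, 3339, 1972 and 758. Both fits leave out the libraries least like their groups, which lowers the estimated spread by construction.

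With each library of a comparison left out in turn, the count ran from 4 to 40 in EAR-13-068, 0 to 4 in EAR-15-025, 1 to 2 in EAR-15-053, 3756 to 4779 in VP16-02-003, 2 to 5075 in VP16-05-014, 3 to 4 between EAR-15-025 and EAR-15-053, 780 to 1271 in EAR pool 13, 430 to 914 in EAR pool 15, 2 to 93 in VP16 pool 2 and 1 to 25 in VP16 pool 5. The number of lists past the test ran from 6 to 9 in EAR-13-068, 3 to 6 in EAR-15-025, 4 to 8 in EAR-15-053, 7 to 11 in VP16-02-003, 3 to 8 in VP16-05-014, 3 to 7 between EAR-15-025 and EAR-15-053, 5 to 8 in EAR pool 13, 6 to 9 in EAR pool 15, 8 to 10 in VP16 pool 2 and 5 to 9 in VP16 pool 5. The light harvesting list in VP16 pool 2, lower by limma's camera (adjusted p = 0.00311), turned to a higher direction without VP16 pool 2 A (adjusted p = 0.776), the cause not tested, and the lowest adjusted p with 1 library left out was 3.69e-09. With an estimated correlation the lists past the test fell to 0 in every comparison, and the cause was not tested. With RLE size factors each number of lists stayed within 1.5 times.

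Interaction contrasts called 5 genes for EAR-15-025 and EAR-15-053 and 72 for EAR-15-025 and VP16-05-014 with library size alone. Without the 4 libraries EAR-13-068 differed from EAR-15-025 in 20 genes, from EAR-15-053 in 10 and from VP16-05-014 in 4571, EAR-15-025 from EAR-15-053 in 11 and from VP16-05-014 in 2576, and EAR-15-053 from VP16-05-014 in 2358. Without the libraries apart by chi-square these numbers were 24, 12, 5542, 6, 2813 and 2696, and EAR-13-068 differed from VP16-02-003 in 6685. With each library left out in turn the counts for EAR-13-068 ran from 3 to 7 with EAR-15-025, 2 to 6 with EAR-15-053, 2757 to 4052 with VP16-02-003 and 35 to 4264 with VP16-05-014. For EAR-15-025 they ran from 3 to 4 with EAR-15-053, 1761 to 3184 with VP16-02-003 and 4 to 2848 with VP16-05-014, for EAR-15-053 from 1570 to 3484 with VP16-02-003 and 1 to 3791 with VP16-05-014, and for the VP16 lines from 153 to 683. The cause was not tested. Interactions were not run with DESeq2 or on fewer groups.

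Numbers of shared calls that moved with a 2-fold minimum did so by construction. VP16-02-003 then shared 20 higher and 52 lower genes with VP16-05-014, 60 and 53 with EAR pool 13 against Col-0, 87 and 60 with EAR pool 15 against Col-0, and 0 and 2 with EAR-13-068. VP16-05-014 shared 4 and 4 with EAR pool 13 and 10 and 8 with EAR pool 15, and the EAR pools shared 145 and 86 with each other. EAR-13-068 shared 0 higher genes with EAR pool 13 and 0 with EAR pool 15, and EAR-15-025 0 higher with EAR pool 13, 0 lower with VP16-02-003 and 1 lower with the contrast of EAR-15-025 and EAR-15-053, which shared 0 lower with VP16-02-003. The other 62 numbers stayed within 1.5 times.

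With the replicate letter as a block EAR-15-025 had 4 called genes, the interaction of EAR-15-025 and VP16-05-014 gave 74, and the other 9 counts of each kind and all numbers of lists stayed within 1.5 times. Of 190 list tests 2 passed in addition, root markers in EAR-15-053 (adjusted p = 0.043) and flavonoid genes in VP16 pool 5 (0.0245), and 2 no longer passed, auxin in EAR-15-053 (0.0512) and iron status in VP16-05-014 (0.0505). Outside EAR pool 15 against Col-0 the libraries share only a letter. As a hint from the data, in VP16 pool 5 against Col-0 6 of 6 libraries correlated best with their own letter, at 0.03, 0.08 and 0.05. Values were followed for genes that are named and for up to 4 members of each list with the smallest adjusted p, each in its comparison. Of these 840 values the block kept 818 on their side of the threshold, library size alone 809, edgeR's RLE size factors 838, DESeq2 787, no filter 827 and no organelle genes 836. The 6 libraries alone kept 739, while 54 lost and 23 gained the call, and the rest of the 840 were absent from that fit. The fits without the 4 libraries and without those apart by chi-square kept 714 and 671, where 123 and 162 gained and 3 and 7 lost it. Over all fits that left out 1 library 4516 values kept their side, 471 lost and 53 gained the call. No value changed direction past the threshold in any of these. In simulated counts 44.8% of 1.5-fold changes were recovered in both EAR-13-068 and VP16-05-014 and 50.7% in VP16 pool 5 against Col-0, so differences of this size may be missed. The simulated groups shared 1 spread per gene and held no library standing apart. The 200 changed genes were drawn anew for each comparison. These shares therefore cannot tell whether depth adds a limit, and the real libraries may allow less.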

Other observations

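The tests of the sulfate list and of the neighbours of AT3G22240 were chosen only after the results were seen, and the tests of adjacent genes and of other splits of the samples were planned before. Genes of sulfate uptake, assimilation and limitation, a list made after the low values of APR1, APR3 and LSU2 were seen and so no independent evidence of its direction, fell in VP16-02-003 in 16 of 24 cases, with a median log2 fold change of -1.86 (limma's camera, unadjusted p = 1.04e-08, and p = 0.0394 with an estimated correlation). SDI2, a low-sulfur response gene, was at -3.34, APK2, an adenylylsulfate kinase gene, at -2.30 and ATPS3, an ATP sulfurylase gene, at -1.79. In VP16-05-014 1 of 24 was lower, with a median of -0.54 (p = 3.43e-05, and p = 0.127 with an estimated correlation), and in EAR-13-068 the median was 0.40 (p = 6.98e-05, and p = 0.149 with an estimated correlation).

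Single genes stood out in single groups and were picked after their values were seen. AT3G01345, a glycoside hydrolase-domain protein gene, was at 246 ± 6.85 CPM in VP16-02-003, 77.4 ± 42.5 CPM in the VP16 pool 2 background (SD, n = 3 each) and below 1 CPM in the means of the other 8 groups, with a log2 fold change of 1.66 between line and pool (SE 0.27, adjusted p = 0.000137 by edgeR). Of the 5 genes on each side of it DEL3 changed past the threshold over the neighbours alone, at -0.48 (adjusted p = 0.0424). The adjacent AT3G01350 was at -0.77 (adjusted p = 0.0662 over the neighbours and 0.0468 over all genes by edgeR). With 29.1% of all genes called in VP16-02-003, such calls are by themselves no sign of a local effect. The antisense RNA AT2G05914 was at 12.6 CPM in EAR-13-068, 5.5 CPM in VP16-05-014 and 1.54 CPM in Col-0. VP16-05-014 C differed from A and B in several lists, with glucosinolate genes higher by a median of 1.84 and flavonoid genes by 1.78 on the log2 scale, and senescence genes at -1.61. The plastid share was 0.564% in A, 1.287% in B and 0.147% in C. Without C, and so with the pair of libraries of the higher plastid share alone, VP16-05-014 differed from its pool in 5075 genes, 2611 higher and 2464 lower, 2489 of them called in the same direction in VP16-02-003 and 28 in the opposite one. Of the glucosinolate genes 14 of 18 were then lower, with a median of -1.26, and of the senescence genes 9 of 17 higher and 1 lower, with a median of 0.74.

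A local effect around AT3G22240 in EAR-15-053 was tested on the 5 genes on each side. Of them 1 was lower past the threshold over these neighbours alone, the adjacent AT3G22235 at 72.4 ± 13 against 247 ± 76.2 CPM (SD, n = 3 each; log2 fold change -1.77, SE 0.36, adjusted p = 0.00055 over the neighbours and 0.211 over all genes by edgeR). PCC1, the next gene, was at -0.43 (adjusted p = 0.543 over the neighbours). In EAR-15-053 AT3G22235 ran from 58.3 to 83.9 CPM, overlapping Col-0 at 66.8 to 147 CPM and VP16 pool 5 at 70.3 to 164 CPM. For AT3G22240 there was no overlap with any other group. A change of more than 1 gene at this locus may be present, although AT3G22235 and AT3G22240 are related and reads shared between them would also lower both. A requirement of at least 2 neighbours was tried after the value of 1 was seen and then given up for the original one. Called genes that are adjacent on a chromosome and change in the same direction numbered 0 in EAR-13-068, where random placement of the calls gave a median of 0 and a 95% bound of 1. They numbered 1029 in VP16-02-003, against 834 and 875, and 7 in VP16-05-014, against 2 and 5, each over 10000 placements. Local effects on neighbouring genes could give the excess in both VP16 lines, but tandem copies and genes regulated together would do so too, and these were not told apart.

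Other divisions of the 6 libraries of each comparison were fitted on those libraries alone. With 10 splits of 3 against 3 no share under 0.05 is possible. In EAR-13-068 the real split called 50 genes, in EAR-15-025 7, in EAR-15-053 1, in VP16-02-003 5516, in EAR-15-025 against EAR-15-053 1, in EAR pool 13 against Col-0 2284 and in VP16 pool 5 against Col-0 1, and the highest other split called 0 in each of these. Of the 50 genes in EAR-13-068 only 17 were among the 46 called with all libraries. Of the 7 in EAR-15-025 only 4 were among the 10 called with all libraries. In EAR pool 15 against Col-0 the real split called 1874 and the highest other 4. In each of these 8 comparisons 1 split of 10, the real one, called as many. If the letters pair the samples in EAR pool 15 against Col-0, 4 splits part all 3 pairs, and the highest other count among them was 0. In VP16-05-014 all 10 splits called 0, the real one included, where the fit to all libraries called 293 and DESeq2 743, with 3871 genes at an unadjusted p under 0.05. In VP16 pool 2 against Col-0 the real split called 2 and 2 of 10 splits called as many. One other, VP16 pool 2 A and B with Col-0 C against the rest, called 30, several times the real count, which points to a structure of the samples. The plastid share followed this split, at 0.132, 0.131 and 0.182% in those libraries and 0.382, 0.643 and 0.568% in pool 2 C and Col-0 A and B. Whether it marks that structure was not tested.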
